A study of Drosophila melanogaster with 2 samples.

How the data were processed

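Polyadenylated RNA was profiled in whole adult male Drosophila melanogaster at 15 days of age. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with the NEBNext Ultra Directional kit, and 51-bp single-end reads were taken on an Illumina HiSeq 1000. The 2 libraries, 1 per group, came from flies carrying the ubiquitous daughterless driver alone (da-Gal4/+, called control) and from flies in which that driver expressed a miR-305 transgene (da-Gal4/UAS-miR305, called miR-305). How many flies went into each library is not given in the sources used here.

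The deposited table holds 1 FPKM value (fragments per kilobase of transcript, scaled to the number of mapped fragments) for each library and each of 15906 features, per the file headers. Per the submitters' processing notes, FastQC 0.11.5, TopHat2 2.0.13 and Cufflinks 2.2.1 were used with the dm6 build, and the strand setting of the counting is not given in the sources used here. Reads from overlapping genes on opposite strands, and reads shared by near-identical paralogs such as the cecropins, the Jonah proteases, the trypsins and the Hsp70 genes, are therefore of uncertain assignment. FPKM divides by an effective length, so a transcript close to the read length receives a large and unstable value per read. The low values did not fall on steps that give whole reads, so the depth of each library is unknown and no counting interval is given. Prosalpha1, a proteasome subunit that all cells use, was listed at 0 in both libraries, so an exact 0 can be a failed estimate and is written here only as listed at 0.

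Features were matched to the Ensembl 115 annotation of the same assembly by symbol or RefSeq synonym, with the gene required to lie in the deposited locus, and 14964 features (94.1%) matched. Each of 634 features held several gene symbols and entered no gene list. Coordinates are 1-based on dm6, and transcript length is that of the longest annotated transcript. The log2 ratio was log2 of (miR-305 FPKM + 1) over (control FPKM + 1), which understates the difference of low genes, for features with a mean FPKM of at least 1 over both libraries. Folds are ratios of the FPKM values without the added 1. A feature was counted as higher or lower at a ratio of at least 2-fold on the log2(FPKM + 1) scale. With 1 library per group no test between groups exists, and no p-value or standard error was computed.

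For each of 31 gene lists fixed before the data were examined, the median log2 ratio was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these 2 libraries only. A list was said to stand apart outside the central 95% of the random medians. Lists of randomly drawn genes would do so in 1.55 of 31 cases. Members that share a tissue or regulator can move together between 2 libraries. The number 1.55 is therefore no measure of chance between flies. The lists covered antimicrobial peptides, immune signalling, stress and detoxification, metabolism, digestion, the reproductive tract, muscle, neurons, photoreceptors, haemocytes, ribosomes and mitochondria. They also covered pathways such as insulin, Notch and p53 signalling. A further 4 lists were written after the values were seen and appear only in the additional observations.

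Genes were named by a rule set before the data were examined: the mir-305 locus and its neighbour, da, w, InR, Pi3K92E, H, Su(H) and p53, the 12 features with the highest and the 12 with the lowest log2 ratio, and up to 4 members of each list with the largest absolute ratio. The 24 features at the extremes included only 1 protein-coding gene, so the same rule was also applied to protein-coding genes with a mean FPKM of at least 10, a choice made after seeing the data. Mst57Db, SP, Dup99B, Acp98AB, Mst84Db, Mtk, IM2, Drs, Drsl4, CG16712, epsilonTry, Amy-p, ninaE, nSyb, PGRP-LB, PGRP-SD, pirk, Rel and the genes of the added lists were named after their values were seen.

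Alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 10, and rescaling to a common median, upper quartile or sum. Limits to protein-coding genes, to transcripts of at least 200 nt and to features above 0 in both libraries, and matching of lists on length as well as expression, were added after seeing the data. The planned comparison of genes with and without miR-305 seed sites in the 3' UTR was not run, because no genome sequence was used here. The calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and the plots used matplotlib 3.10.9. They were tested on simulated data in which a second library for the miR-305 against control comparison was drawn from the control values with log-normal noise (SD 0.25 on the log2 scale, 11945 features past the filter). Of 200 altered genes, the 2-fold rule recovered 59% of those set to 2.5-fold and 96% of those set to 4-fold. It took up 0 unaltered genes. The real log2 ratios spread more widely, with an SD of 0.69 at a mean FPKM of at least 10, which includes any real differences. These simulated shares follow from the smaller simulated noise and do not describe the real counts past 2-fold. A list of 20 genes shifted by 0.5 came out at percentile 100. Of 200 unshifted lists of randomly drawn genes, 10 fell outside the central 95%.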

Results

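Gene expression was compared between whole 15-day-old adult males that overexpressed the microRNA miR-305 under a ubiquitous driver and males that carried the driver alone. Each group had 1 library, so no difference between the libraries has a replicate check. The study's title places the comparison in a search for the messenger RNA targets of miR-305 and its part in ageing. The control library had 14389 of 15906 features above 0, with FPKM values that summed to 967511. The miR-305 library had 14241 features above 0, with values that summed to 1176985. Sequencing depth is unknown for both.

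The mir-305 stem-loop (chromosome 2L, 7425972 to 7426044, 73 nt) had 546 FPKM in the miR-305 library and was listed at 0 in the control library. It had the largest difference in FPKM among 172 annotated microRNA stem-loop features, followed by mir-4965 at 299 FPKM against a listed 0. Most stem-loops (148 of 172) were listed at 0 in both libraries. The feature that holds mir-275, the neighbour with which mir-305 is clustered, had 0.34 FPKM in the miR-305 library and 0.55 FPKM in the control library. The gene whose enhancer drives the transgene, da, had 10.8 and 12.6 FPKM. The feature that holds the eye colour gene w, a common transgene marker, had 46.3 and 39.5 FPKM.

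The median log2 ratio of genes for male seminal proteins and fat body storage proteins lay above that of random lists of like expression, with values of 0.70 and 0.48. The median log2 ratio of antimicrobial peptide, testis and photoreceptor genes lay below, with values of -0.64, -0.38 and -0.22. Digestive enzymes (0.30) and odorant-binding proteins (0.34) also stood above. With the same sum in both libraries these medians were 0.02 and 0.09. Those of the seminal and fat body lists were 0.42 and 0.20, and each still stood above its random lists. Most members of these lists lay within 2-fold. Among 11936 features with a mean FPKM of at least 1, 282 were at least 2-fold higher, 208 were at least 2-fold lower and 11446 (95.9%) lay within 2-fold. The median log2 ratio was -0.03 over these features and 0.01 over the 6747 features with a mean FPKM of at least 10. Across genes, the log2(FPKM + 1) values of the libraries had a Pearson r of 0.954, where genes are not independent replicates. Of the features past 2-fold, 57.6% were higher, and this share was 32.8% (179 higher, 367 lower) when both libraries were scaled to the same sum, which shifted the median of all features by -0.25.

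**Figure D1:**
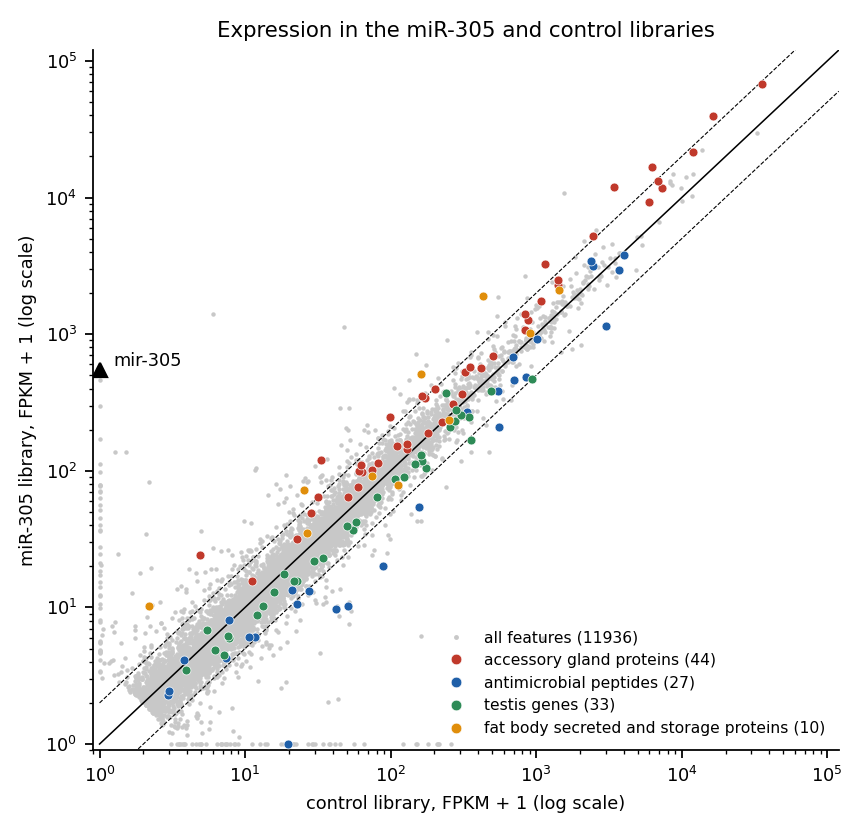
FPKM + 1 in the control library (x axis, log scale) and in the miR-305 library (y axis, log scale) for 11936 features with a mean FPKM of at least 1, with 1 point per feature, a solid line at equality and dashed lines at 2-fold. Accessory gland genes (red) lie on or above the solid line, with a median log2 ratio of 0.70, and testis genes (green) lie mostly below it, with a median of -0.38. The triangle marks mir-305, at 546 FPKM against a listed 0.

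The features at the extremes were mostly short noncoding RNAs. Of the 24 features with the highest and lowest ratios, 18 had transcripts under 200 nt and 21 were listed at 0 in one library. Among all 168 expressed features under 200 nt, 114 (67.9%) were past 2-fold in either direction, against 3.09% of the other annotated features. Box C/D small nucleolar RNAs, many of which guide ribosomal RNA methylation, stood at both ends. The RNA snoRNA:U27:54Ea had 460.1 FPKM in the miR-305 library and was listed at 0 in control. In contrast, snoRNA:Or-CD4 was listed at 0 in the miR-305 library and had 259 FPKM in control. A pair of longer noncoding RNAs on the X chromosome also differed in opposite directions. CR40469 had 1396 FPKM in the miR-305 library and 5.01 in control, and CR34335 had 4.98 and 1119 FPKM.

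The only protein-coding gene among those 24 was CG14406 (X, 14909873 to 14910845), with 136 FPKM in the miR-305 library and 0.27 in control. Among protein-coding genes with a mean FPKM of at least 10, the highest ratios after it belonged to CG13905 (3L, 902898 to 903810; 1129.8 against 46.7 FPKM), Os-C, which encodes a protein of the olfactory organs (33.6 against 1.09), CG33346 (35.1 against 3.95), CG42782 (10732.5 against 1558) and the serpin Spn77Bb (288 against 50.9). The other genes among the 12 highest included CG42807 (718 against 149), tobi, a target of brain insulin (1901 against 432), and the cytochrome P450 gene Cyp4e3 (41.8 against 8.77). The lowest ratios belonged to CG11893 (3R, 25289889 to 25291366; 1.14 FPKM in the miR-305 library and 42.7 in control), CG7298 (3L, 20202070 to 20203687; 1.04 and 35.9), CG43773 (3.65 and 31.9) and CG5550 (7.61 and 43.3). The small heat shock gene Hsp23 (41.6 and 160.1) and the metallothionein MtnE (12.7 and 44.1) were also among the 12 lowest.

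Most genes of the antimicrobial peptide list were lower in the miR-305 library. Of 27 expressed members, 9 were at least 2-fold lower, 0 were at least 2-fold higher and 23 had a ratio below 0. Their median log2 ratio was -0.64, at percentile 0 of the matched random lists, and it was negative under every scaling that was tried (-0.90 with the same sum). The diptericins, which act against Gram-negative bacteria, had 9.16 FPKM in the miR-305 library against 49.9 in control for Dpt (2R, 18865765 to 18866260) and 19.1 against 88.2 for DptB, which is 5.45-fold and 4.63-fold lower. The attacin gene AttC was 4.72-fold lower (8.78 against 41.5). Drsl1, a drosomycin-like gene, was listed at 0 against 18.9 FPKM. The antifungal peptide gene Mtk (208 against 558) and the Bomanin gene IM2 (1153 against 3013) were lower too, while the drosomycin gene Drs was nearer to equal (385 against 547). Drsl4 (3406 against 2361) and CG16712 (3157 against 2453) were higher. Anp, an antimicrobial peptide gene that the fixed list did not hold, was also higher and is given with the seminal proteins below. The genes that sense bacteria and fungi and carry the signal did not show this difference. Their 26 expressed members had a median of -0.03 (-0.29 with the same sum), at percentile 33.8, with 0 members past 2-fold, and the recognition genes GNBP3 (78.6 against 48.4) and PGRP-LC (45.5 against 57.9) lay on opposite sides. Of 9 expressed haemocyte and melanisation genes, 1 was at least 2-fold higher, NimC1, a phagocytosis receptor (15.1 against 5.97), and the median was 0.16, at percentile 93.1, and -0.08 with the same sum in both libraries. NimC1 fell short of 2-fold with a pseudocount of 5 (0.88) and with the same sum (0.95).

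Genes for seminal fluid proteins of the male accessory gland were higher in the miR-305 library. All 44 expressed members had a ratio above 0, and 10 were at least 2-fold higher. With the same sum in both libraries, 38 of the 44 stayed above 0, 6 were at least 2-fold higher and the median was 0.42. The median log2 ratio was 0.70, which is a 1.63-fold higher FPKM + 1, at percentile 100. Acp54A1 (2R, 17133445 to 17133750) had 11989.5 FPKM against 3452, the serpin gene Acp76A had 119 against 32.3, and Sfp96F had 3267 against 1148. The sex peptide gene SP, whose product alters female behaviour after mating, had 21688 FPKM against 11863. The most abundant feature of both libraries was a member, Mst57Db, with 67539 FPKM in the miR-305 library and 35629 in control. The list made up 18.4% of all FPKM in the miR-305 library and 11.2% in the control library. Testis genes were lower over the same pair of libraries. Of 33 expressed members 31 had a ratio below 0, the median was -0.38, at percentile 0, and 1 was at least 2-fold lower. With the same sum the median was -0.64 and 3 were at least 2-fold lower. The gene past 2-fold with the deposited scaling was Mst84Dd, which encodes a sperm tail protein (166 against 355 FPKM). Its neighbour Mst84Da had 469 against 932 FPKM, the spermatid chromatin gene Mst77F had 104 against 175, and Mst84Db was higher (370.4 against 240.2). Of 22 egg and yolk genes only 2 were expressed, with a median of -0.06, at percentile 51.6.

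**Figure D2:**
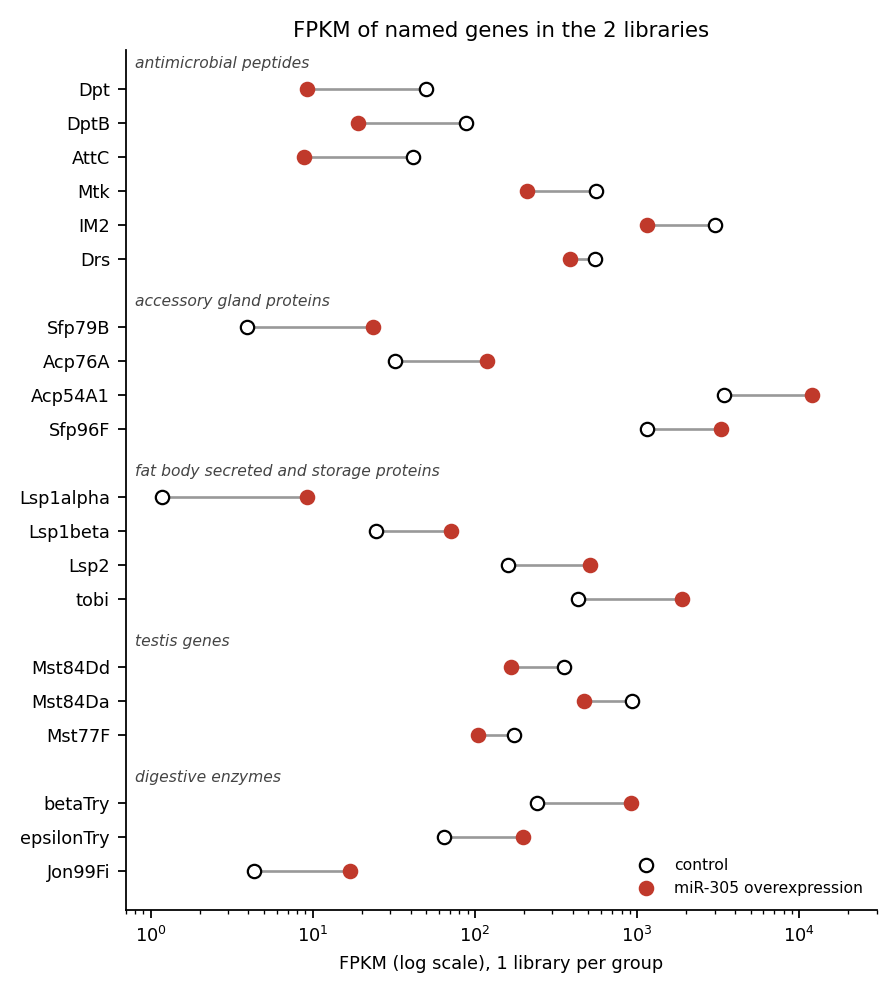
FPKM (x axis, log scale) of 20 named genes in the control library (open circles) and the miR-305 library (filled circles), 1 library per group, with genes grouped by list. The 6 antimicrobial peptide genes and the 3 testis genes are lower in the miR-305 library, as in Dpt at 9.16 against 49.9 FPKM. The 4 accessory gland, 4 fat body and 3 digestive genes are higher, as in Lsp2 at 514 against 159 FPKM. The genes were picked in the direction of their list's median. Members that go the other way, such as Drsl4, CG16712, Mst84Db and Jon66Ci, are not shown.

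Fat body secreted and storage proteins and digestive enzymes were also higher. Of 10 expressed fat body genes 4 were at least 2-fold higher and 0 lower, with a median of 0.48, at percentile 99.7, and with the same sum in both libraries the median was 0.20 and 7 members lay above 0. The larval serum proteins, which store amino acids, had 514 FPKM against 159 for Lsp2, 70.8 against 24.6 for Lsp1beta and 9.21 against 1.18 for Lsp1alpha. Among 51 digestive enzymes 6 were at least 2-fold higher and 3 lower, with a median of 0.30, at percentile 100, which was 0.02 with the same sum in both libraries. This median lay 0.33 above that of all features with the deposited scaling and 0.29 above it with the same sum. The trypsin genes betaTry (912 against 242) and epsilonTry (198 against 64.6) and the amylase Amy-p (434 against 221) were higher, and the protease Jon66Ci was lower (1.90 against 11.2). Lipid metabolism had a median of 0.25, at percentile 95.9, and carbohydrate metabolism a median of 0.20, at percentile 85.9, with 0 members of either past 2-fold. Both medians were negative (-0.03 and -0.08) with the same sum, where the median of all features was -0.27. There they lay 0.24 and 0.19 above all features, against 0.27 and 0.23 with the deposited scaling. The genes farthest from equal were ATPCL, which makes acetyl-CoA for fat synthesis (263 against 164), and Pgm, which interconverts glucose phosphates (383 against 233).

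Among genes of detoxification, 72 expressed cytochrome P450s had a median of 0.17, at percentile 100, with 3 members at least 2-fold higher and 2 lower, and this median was -0.10 with the same sum in both libraries. That setting put the median of all features at -0.27. The medians of cytochrome P450s, glutathione S-transferases and antioxidant enzymes lay 0.17, 0.25 and 0.17 above it, against 0.20 for each with the deposited scaling. The neighbours Cyp4p2 (18.1 against 4.86 FPKM) and Cyp4p1 (7.05 against 22.8) lay on opposite sides. Cyp12d1-d had 4.50 FPKM and was listed at 0 in control, and it shares reads with a near-identical copy and fell short of 2-fold with a pseudocount of 5 (0.93). Glutathione S-transferases of the D and E classes had a median of 0.17, at percentile 96.3, and -0.03 with the same sum. GstE10 (56.1 against 15.8) and GstD8 (61.8 against 18.05) were at least 2-fold higher, and GstD10 (5.55 against 12.6) was at least 2-fold lower, though not with a pseudocount of 5 (-0.74). Antioxidant enzymes had a median of 0.17, at percentile 92.9, with 0 of 21 past 2-fold and catalase (Cat) at 476 against 374 FPKM, and their median was -0.10 with the same sum. The 4 metallothioneins, which bind metals, had a median of -0.54, at percentile 0.20 (-0.82 with the same sum), with MtnE lower and MtnB higher (57.6 against 28.0), the latter short of 2-fold with a pseudocount of 5 (0.92) and with the same sum (0.74). The most abundant of them, MtnA, had 10224 against 11856 FPKM. Heat shock proteins had a median of -0.04, at percentile 16.0, and -0.31 with the same sum. Of 15 expressed members 1 was at least 2-fold lower with the deposited scaling, Hsp23 (41.6 against 160.1 FPKM, log2 ratio -1.92). Hsp26 (65.8 against 117 FPKM) also passed 2-fold with the same sum (-1.09), and Hsp83 had 190 against 290. Of 4 Turandot stress genes, TotX was 2.40-fold higher (126 against 52.3; log2 ratio 0.97 with the same sum) and TotA was near equal (417 against 390), and the median of 0.12, at percentile 59.5, was -0.16 with the same sum.

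Lists with many genes of the head lay on opposite sides. Photoreceptor genes had a median of -0.22, at percentile 0.20 (-0.50 with the same sum), with 0 of 20 past 2-fold, and the corneal protein gene retinin (120 against 225 FPKM) and the phospholipase gene norpA of phototransduction (19.6 against 32.7) were lower. Of these 20, retinin passed 2-fold with the same sum (-1.18) and ninaA with a pseudocount of 0.1 (1.07). The main rhodopsin gene ninaE was higher (2685 against 2206). Neuronal genes had a median of -0.27, at percentile 1.65, with 11 of 15 below 0, and this median no longer stood apart with a pseudocount of 5 (-0.10), without a filter (-0.22) or with the same sum (-0.43). Long transcripts tended to be lower: the 1600 expressed protein-coding genes longer than 4000 nt had a median of -0.10 and quartiles of -0.25 and 0.03. The neuronal list had a median transcript of 6331 nt. Matched on length as well, its median lay at percentile 0.595, with a random range of -0.24 to 0.03. Syt1 had 6.06 against 9.12 FPKM and Appl 6.72 against 9.66, whereas nSyb was near equal (38.7 against 39.9). Odorant-binding proteins were higher, with a median of 0.34, at percentile 99.99, and 7 of 29 members at least 2-fold higher. With the same sum in both libraries the median was 0.09, still above the random lists. There 2 members were at least 2-fold higher and 1 was lower. Obp83a (5.63 against 0.25) and Obp83b (9.34 against 1.29) differed most, followed by Obp8a (37.7 against 15.4), whose product is also known from seminal fluid and which fell short of 2-fold with the same sum (0.97). Obp99a and Obp99b are members of the fat body list as well. Clock genes had a median of 0.10, at percentile 87.2 (-0.17 with the same sum), with Pdp1 1.63-fold lower (14.7 FPKM in the miR-305 library, log2 ratio -0.67) and cry higher (80.6 against 65.0).

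**Figure D3:**
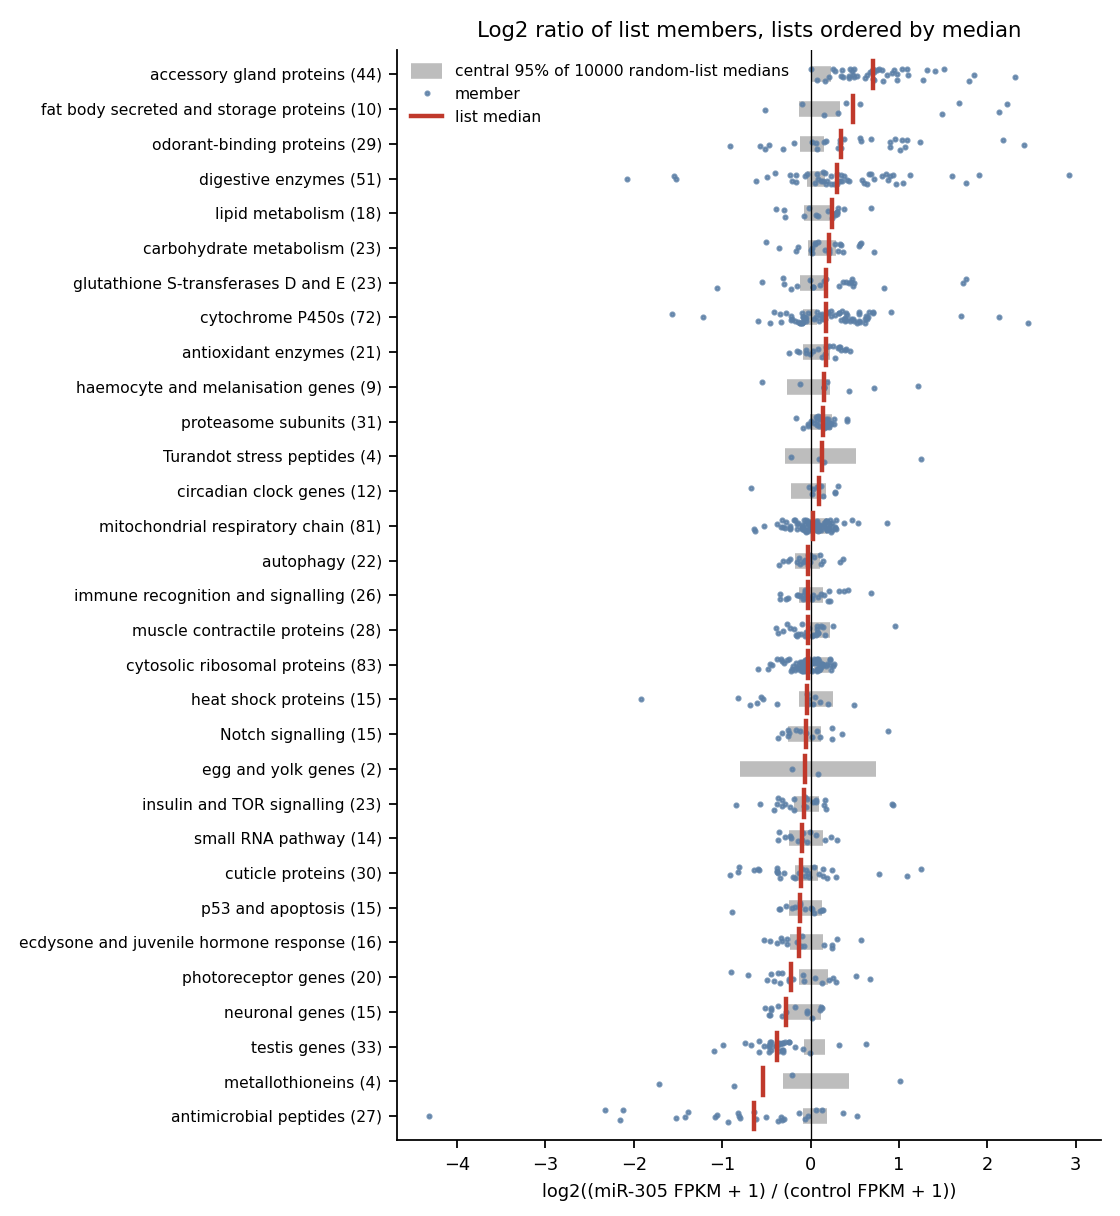
Log2 ratio of FPKM + 1 (miR-305 over control, x axis) of the expressed members of 31 gene lists, with 1 point per gene, a red bar at the list median, a grey bar over the central 95% of 10000 random-list medians, and the number of members in parentheses. Medians run from -0.64 (antimicrobial peptides) to 0.70 (accessory gland proteins). With the same sum in both libraries 10 of the 14 positive medians are negative, and those of accessory gland, fat body, digestive and odorant-binding genes stay positive. That scaling shifts the median of all features by -0.25, so a change of sign need not be a change relative to other features.

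The medians of the insulin and TOR, Notch, p53 and apoptosis, and autophagy lists lay inside the range of the random lists. A list median cannot show an effect of miR-305 on single targets or on translation, and the seed-site comparison was not run. With the same sum in both libraries, which shifted the median of all features by -0.25, the medians were -0.33 for insulin and TOR signalling, -0.27 for Notch signalling, -0.37 for p53 and apoptosis and -0.29 for autophagy. The insulin and TOR list had a median of -0.08 with the deposited scaling, at percentile 29.8. Of its 23 members 0 were past 2-fold, although Ilp5 passed with a pseudocount of 0.1 (1.12) and Pi3K21B with the same sum (-1.09). InR, the insulin receptor gene, had 1.09 FPKM in the miR-305 library and 2.11 in control, which is 1.93-fold lower. Pi3K21B, the adaptor subunit of the kinase downstream of it, was 1.92-fold lower (6.29 against 12.1), whereas its catalytic subunit Pi3K92E was near equal (8.31 against 8.83). The insulin-like peptide genes Ilp2 (47.5 against 24.5) and Ilp5 (6.59 against 2.98) were higher. Notch signalling had a median of -0.05, at percentile 55.5, with Hairless (H) at 2.52 against 2.94 FPKM, Su(H) at 3.51 against 3.19 and the Notch target E(spl)mbeta-HLH at 6.29 against 2.97. The list of p53 and apoptosis genes had a median of -0.12, at percentile 20.6, with p53 at 6.26 against 8.22 FPKM and Corp, a p53 target, at 0.96 against 2.63. Autophagy genes had a median of -0.02, at percentile 52.1, with Atg4b at 7.92 against 5.93. The small RNA list had a median of -0.09, at percentile 30.5 (-0.36 with the same sum), with drosha at 4.91 against 3.81 FPKM, and the median was -0.06 without tai and blp, which are not small RNA factors although the fixed list held them. Ecdysone and juvenile hormone response genes had a median of -0.13, at percentile 15.9 (-0.38 with the same sum), with EcR at 1.503 against 2.61.

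With the deposited scaling, ribosomal, respiratory chain and muscle genes had medians close to 0. The 83 cytosolic ribosomal protein genes had a median of -0.03 with 0 members past 2-fold, at percentile 0.01 of random lists of like abundance, whose medians lay between 0.04 and 0.21. The 81 respiratory chain genes had a median of 0.02, at percentile 3.32, and the 28 muscle contractile genes a median of -0.03, at percentile 4.82, again with 0 members past 2-fold. With the same sum these medians were -0.31, -0.26 and -0.31, and 0 of the 83 ribosomal protein genes lay above 0. Proteasome subunits had a median of 0.15, at percentile 71.4, with 27 of 31 members above 0, and -0.13 with the same sum. Their largest ratio was that of Prosbeta2 (157 against 118 FPKM). Cuticle proteins had a median of -0.11, at percentile 14.1, with 2 of 30 members at least 2-fold higher, Edg91 (3.79 against 1.02) and Cpr66D (11.1 against 4.69), of which both fell short with a pseudocount of 5 (0.55 and 0.73) and Cpr66D also with the same sum (0.83). In the other direction, Cpr78Cc passed 2-fold with a pseudocount of 0.1 (-1.75) and with the same sum (-1.01), and Cpr49Ae with the same sum (-1.09), where the list median was -0.37. Of the 31 lists, 5 stood above and 6 below the central 95% of random lists, and 20 lay inside.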

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

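The limits to protein-coding genes, to transcripts of at least 200 nt and to features above 0, and the matching on length, were chosen after seeing the data. No paired analysis was possible because each group had 1 library and no test was made. Comparisons set before the data were examined but not run were the deposited 95% limits and quantification status, which the table used here does not hold, and every seed-site comparison, which needs a genome sequence.

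The counts of features at least 2-fold higher and lower (282 and 208) were 366 and 332 with a pseudocount of 0.1, 175 and 102 with a pseudocount of 5, 180 and 91 at a mean FPKM of at least 10, 179 and 367 with the same sum, and 163 and 86 among protein-coding genes. Fewer features entered under the stricter filters, and the same sum divides the miR-305 values by a larger total. The accessory gland list made up 18.4% of that total and 11.2% of the control total. The median of all features was -0.27 with the same sum. A list median below 0 under this setting need not lie below the other features. The remaining settings left the counts of higher and of lower features within 1.5 times. Of 11 lists outside the central 95%, 9 kept their side and sign under every setting. The cytochrome P450 median reversed to -0.10 with the same sum, although it stayed above the random lists. The neuronal median of -0.27 moved inside the random range at -0.10 with a pseudocount of 5, at -0.22 without a filter and at -0.43 with the same sum; the cause was not tested. Among lists inside the range, glutathione S-transferases moved above it with a pseudocount of 0.1 and with the same sum, and lipid metabolism did so when lists were matched on length. Of 177 named genes, 153 kept their side of 2-fold throughout. The 84 past 2-fold all kept their sign under every setting, and 8 of the others changed sign, all with the same sum. Unknown depth limits most the features under 200 nt and those near 1 FPKM, for which the number of reads behind a value cannot be given.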

Other observations

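The tests of explanations in this part, and the antennal, neuropeptide, immune regulator and further seminal protein lists, were chosen after the values were seen, while the accessory gland, testis, fat body and antimicrobial lists were fixed before. Os-C and a10, which were among the genes with the highest ratios, are known from the antenna, and a list of antennal genes was gathered around them. Of its 12 expressed members, 6 of them also in the odorant-binding protein list, 11 had a ratio above 0 (8 with the same sum), which the choice of members favours. Os-C had 33.6 FPKM against 1.09, a10 had 26.4 against 5.06 and Obp69a had 6.63 against 2.77. The olfactory co-receptor gene Orco had 1.02 against 0.52, a mean below the filter, and so is not among the 12. Of 40 expressed neuropeptide and hormone precursors, likewise gathered after values were seen, 28 had a ratio above 0 and 3 were at least 2-fold higher, with a median log2 ratio of 0.23 that was -0.03 with the same sum. Ilp2, Ilp3, Ilp5, Ilp6, Akh and Pdf among them also belong to lists fixed before. CCAP had 6.73 FPKM against 1.65, and Pburs (6.85) and AstCC (2.39) were listed at 0 in control. Dsk had 46.2 against 28.9 FPKM and Dh31 14.8 against 7.94, while CCHa2, a nutrient-dependent peptide gene, was lower (94.3 against 168).

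Loci that hold other microRNAs differed in both directions, with 7 stem-loops, mir-305 included, above 0 only in the miR-305 library and 6 only in control. The feature let-7,let-7-C,mir-100,mir-125 had 23.4 FPKM against 0.33, and CR43270,mir-958 had 137 against 0.53. In the other direction, mir-4985 and mir-966 were listed at 0 in the miR-305 library and had 64.8 and 43.8 FPKM in control. Among all expressed features under 200 nt, 114 of 168 (67.9%) were past 2-fold in either direction, so single stem-loop values are unstable. A feature with several genes does not show which of them the reads came from.

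Accessory gland genes were higher in all 44 expressed members, and the 8 members of at most 300 nt had a median of 1.17. All 56 expressed protein-coding genes of at most 300 nt, these members included, had a median of 0.43. Short transcripts are argued against as the whole cause, since 11 members longer than 600 nt had a median of 0.49, at percentile 99.86 of random lists matched on expression and length. A larger share of RNA from the whole male reproductive tract is argued against by the testis median of -0.38. More RNA from the accessory gland and ejaculatory duct may account for part of the difference. With the deposited scaling, 10 of 10 expressed seminal proteins outside the list (100%) had a ratio above 0. With the same sum 7 of 10 did, and all 10 still lay above the median of all features. Among them were Peb, a protein of the ejaculatory bulb (3660 against 1847 FPKM), and Anp (5811 against 2594). Anp is also an antimicrobial peptide gene. Because Peb belongs to the bulb, these values do not single out the gland and duct. An effect of miR-305, mating state and fly-to-fly differences stay open, as untested with 1 library per group.

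Most genes of the antimicrobial peptide list were lower, while the list of the fat body, a main source of them, had a median of 0.48. With the same sum that median was 0.20. Of the 10 expressed fat body genes, Lsp1alpha, Lsp1beta, Lsp2 and tobi were past 2-fold. Such genes can differ by their own regulation, so the list cannot show whether less fat body RNA was present. Short transcripts are argued against, because the antimicrobial median of -0.64 lay below -0.15, the lower end of the central 95% of random lists matched on expression and length. Less immune activation in the miR-305 flies could explain the difference, but 7 regulators that immune signalling induces, all members of the immune recognition and signalling list, had a median of 0.082 and quartiles of -0.06 and 0.18 (median -0.20 with the same sum), with PGRP-LB at 34.6 against 27.5 FPKM, PGRP-SD at 38.5 against 33.2 and pirk at 41.2 against 43.0. These genes go both ways, and how strongly either set is induced was not measured. Less activation and an effect of miR-305 on the peptide genes therefore cannot be told apart. The microbes that each group of flies carried were not measured.

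Of the expressed protein-coding genes, 43 had log2 ratios of at least 2 in size, 26 higher and 17 lower. Few reads on short or low transcripts may explain part of them: 15 of the 43 had both a mean FPKM of at least 10 and a transcript of at least 500 nt, and without the depth the rest cannot be judged. A chromosome segment that came with the transgene would gather these genes on 1 arm, and the fullest arm, 3L, held 13 of them, against a median of 12 on the fullest arm in random draws (percentile 65.6). Those draws took whichever arm was fullest, so 3L was not judged against its own size. It holds 1981 expressed protein-coding genes, whereas the largest arm, 3R, holds 2563 and 10 of the 43. A segment that holds a few of them stays open. Differences in strain background between the parents of the groups, which could silence single genes such as CG14406 or CG11893, were not tested.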
